A study of Homo sapiens with 6 samples.

How the data were processed

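RNA-seq libraries from 6 Calu3 samples were analysed, 3 treated with negative control siRNA and 3 with BRD8 siRNA. Groups and replicate numbers were taken from the sample titles. The labels name Calu3 in every sample, while the shared extraction protocol speaks of another kind of bronchial epithelial cell, and the sample titles were followed. Libraries were made from total RNA with the TruSeq RNA v2 kit, which does not mark strand, and were sequenced from a single end, per the labels.

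The submitters' processing notes name STAR 2.6, featureCounts 1.6.3 of the Subread package, DESeq2 1.22.1 and the genome build hg19. The annotation, the strand setting and any filter are not given in the sources used here. The deposited table held 26364 genes. Its expression values are a normalized signal, counts per gene that the authors divided by a size factor for each library. Beside them stand the deposited comparison of the authors, with a mean, a log2 fold change, its standard error, a test score, a p-value and an adjusted p-value, and a yes or no call per gene. The sign of the authors' test score is opposite to that of their fold change, which is coded as BRD8 over control and was checked against the group means. The header of the call column in the deposited table names a fold of 1.5 and an adjusted p of 0.005, but the 972 calls match an adjusted p under 0.01 for every gene, while 0.005 gives 917. The deposited table holds a spreadsheet error in place of the comparison for 4756 genes, which are the genes with 0 reads in all libraries. Of the gene symbols 28 look like dates, as spreadsheets write them, and these were not named. Every line of the table named a gene.

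Whole reads were recovered from the normalized counts by finding the value of 1 read in each library, and 100% of values came out whole within 0.01. The recovered reads per library ranged from 33640814 to 37896467, and a floor of 3 reads corresponds to between 2.84 and 3.24 normalized counts. This floor covers counting error only, since reads without molecular identifiers are not independent molecules. The 10 most abundant genes took 5.02% to 5.89% of the reads. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 6.63 to 51.9 within groups, the largest between control libraries 1 and 2, so each library counted once.

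Because the values were normalized rather than raw, the test written for that case was used: limma 3.58.1 in R 4.3.3, with a variance trend, on log2 of the normalized count plus 1, over 15354 genes with a mean of at least 10. Fold changes are therefore on the log2(value + 1) scale and understate the change of low genes. The design held the treatment alone, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. As an alternative the quasi-likelihood test of edgeR 4.0.16 on the recovered reads called 2926 genes, 2831 of them also called by limma. The authors' deposited table has 3233 genes with an adjusted p under 0.05, of which 2793 were shared. An unadjusted p under 0.05 was found for 5084 genes. Among the changed genes 2918 had groups that did not overlap, as did 36.8% of the genes tested, where chance gives 10%.

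Fixed before the data were examined were 32 gene lists, the tests and the naming rule. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at a correlation estimated in each list and with fry beside it. Fry tests whether the members of a list move on balance in 1 direction and does not compare them with other genes. Genes are named by rule: BRD8, the 12 largest rises and 12 largest falls among changed genes with a mean of at least 50 normalized counts and groups that did not overlap, and up to 4 members per list with the smallest adjusted p, or 2 where none passed. BRD8 counts also among the 12 falls. Some genes that the rule names are not reported here. The values per group are means ± SD over 3 libraries.

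GENCODE v29 was used for transcript length, GC content, untranslated regions and overlaps of exons. It is on another build than the data, so no coordinates are given. Of the gene symbols 23747 matched it directly, 740 through older symbols and 26 through current ones, and 1851 did not match. Of the 148 genes named by the rule, 50 have exons that overlap another gene, 42 of them on the opposite strand. Among those with values in the text are CDC25C (FAM53C), NCAPG (LCORL), PRIM1 (NACA and HSD17B6), IFIT2 (LIPA), CXCL6 (PPBPP1), FOXA1 (TTC6), TGM2 (RPRD1B), RSPH1 (SLC37A1) and VIL1 (USP37). Reads in such overlaps cannot be told apart without strand, and counts of close paralogs such as the galectins, keratins, CEACAM and AKR1C genes are uncertain.

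The model was tested on simulated counts drawn from the means and depths of these libraries over 15354 genes, some of them changed by known folds. In that simulation limma recovered 65% of genes changed 1.5-fold and 86% of those changed 2-fold, and 8.48% of its calls were unchanged genes. Far fewer genes were changed in it than were called in the data, and it held no trend with length and GC. These rates need not hold for the data. The scan of 3' untranslated regions for words of 7 bases, run with Python 3.11.15, was tested on simulated shifts and on shuffled values of 13330 genes.

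Alternatives were other pseudocounts, filters and scalings, the replicate number as a block, limma-voom, DESeq2 1.42.0 and edgeR on recovered reads with other factors and filters, a minimum fold, each library left out in turn, and, added after the data were seen, edgeR with TMM factors, the authors' own comparison, quantile normalization for the lists and a trend with length and GC taken out of each library.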

Results

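Gene expression was measured by single-end RNA-seq in Calu3, a human lung adenocarcinoma line of airway epithelial character, after transfection of siRNA against the bromodomain gene BRD8 or of a negative control siRNA. Each treatment had 3 libraries, each labelled with 20 nmol of siRNA. BRD8 encodes a subunit of the TIP60/NuA4 histone acetyltransferase complex. The comparison asks which transcripts differ after siRNA against it in lung epithelial cells. The design holds 1 reagent against BRD8, so for the other genes its effects apart from BRD8 loss cannot be told from those of BRD8 loss. The deposited table held normalized counts for 26364 genes, from which whole reads were recovered. The control libraries held 37081766, 33640814 and 35086661 reads assigned to genes, and the BRD8 libraries held 34427104, 37896467 and 36906424. The labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

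BRD8 itself fell in each of the 3 BRD8 siRNA libraries. Its level was 2916 ± 158 normalized counts in the control libraries and 1184 ± 117 in the BRD8 siRNA libraries (mean ± SD, n = 3 each), a 2.47-fold difference. The log2 fold change was -1.30 (SE 0.0904, adjusted p = 1.13e-04). The authors' deposited table gives a log2 fold change of -1.30 for BRD8, with a standard error of 0.105. The gene lies on chromosome 5, where its exons overlap those of KIF20A on the opposite strand, and the library kit does not mark strand. KIF20A, a mitotic kinesin, fell as well, from 2878 to 1807 normalized counts. The groups parted along the first principal component, which held 53.1% of the variance. The second component, with 20.6%, set control library 2 apart from the other 5 libraries.

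**Figure D1:**
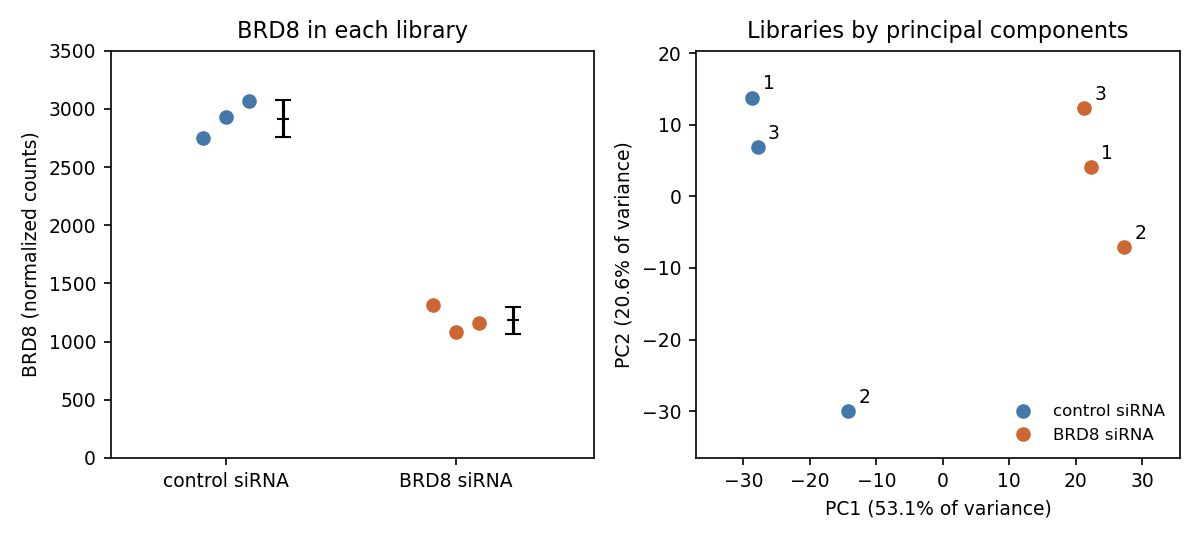
Left, BRD8 in normalized counts (vertical axis) in each library of the control siRNA and BRD8 siRNA groups, with the mean and SD of 3 libraries beside them, and right, the 6 libraries on the first and second principal components, numbered by replicate. The BRD8 siRNA libraries lay between 1084 and 1312 normalized counts and the control libraries between 2751 and 3067, while control library 2 lay apart from the others on the second component.

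The transcriptome of BRD8-depleted cells shifted in both directions, with most of the larger changes upward. Of 15354 genes tested, 1549 rose and 1371 fell (limma, adjusted p under 0.05). At 2-fold or more, 278 rose and 51 fell. The largest rise met by the naming rule was that of LINC01133, a long noncoding RNA, from 39.4 ± 13.2 to 277 ± 42.2 normalized counts (log2 fold change 2.82, SE 0.241, adjusted p = 2.43e-04). The largest fall was that of ADAM19, a membrane metalloprotease, from 136 ± 12.4 to 31.3 ± 5.31 (log2 fold change -2.09, SE 0.172, adjusted p = 1.97e-04), although its exons overlap those of CYFIP2 on the other strand.

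Among the other large rises were ANXA13, an annexin of epithelial cells, from 687 ± 96.1 to 3342 ± 370 normalized counts, and the synaptotagmin SYT12, from 102 ± 6.96 to 484 ± 30.0. RARRES2, which encodes chemerin, rose by 2.27 on the log2 scale, GC, the vitamin D binding protein, by 2.23, and the scavenger receptor SCARA3 by 2.21. PSG4, a pregnancy-specific glycoprotein, rose by 2.41, the peptidylarginine deiminase PADI1 by 2.13, SHISA2 by 2.04 and the bHLH factor HES2 by 2.00. The galectin genes LGALS7 and LGALS7B rose by 2.21 and 2.16, but they are near-identical copies and their reads cannot be assigned to either with certainty. PSG4 also has close paralogs. Their adjusted p-values lay between 2.07e-05 for SYT12 and 4.90e-04 for RARRES2.

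The transcription factor RUNX3 fell from 237 ± 27.6 to 57.7 ± 3.45 normalized counts (log2 fold change -2.02, SE 0.135, adjusted p = 1.01e-04). The membrane-type matrix metalloprotease MMP16 fell by 1.65 on the log2 scale, and DDC, the aromatic amino acid decarboxylase, by 1.52. SYT11 fell by 1.31, the adhesion receptor ADGRL3 by 1.29, the basement membrane protein NID1 by 1.29, and MMP17 by 1.27. CR2, a receptor of complement fragments, fell from 276 ± 47.8 to 117 ± 15.9 normalized counts and SOWAHA from 78.3 ± 2.27 to 33.2 ± 2.85. For MMP17 the adjusted p was 0.0360 with all libraries, 0.0731 without control library 1, 0.114 without control library 3 and 0.0632 without BRD8 library 3. The exons of MMP16, DDC and ADGRL3 overlap antisense genes.

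**Figure D2:**
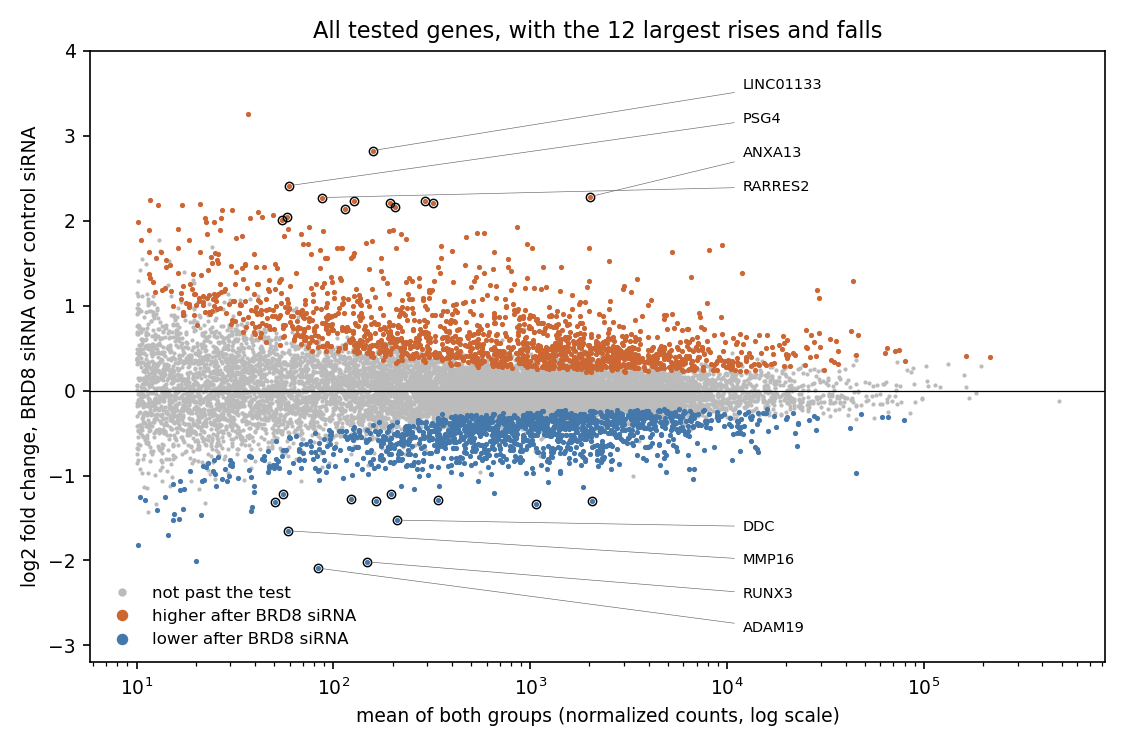
Log2 fold change of BRD8 siRNA over control siRNA (vertical axis) against the mean of both groups in normalized counts (horizontal log axis), with 1 point per tested gene, orange where it rose, blue where it fell and grey where it did not pass, and circles on the 12 largest rises and 12 largest falls of the naming rule, with names on the 4 largest of each. Changes beyond 1 on the log2 scale were mostly rises, 278 against 51 falls.

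The number of changed genes depended on the libraries used. Against 2920 genes with all libraries, leaving out control library 2 gave 5229, control library 1 gave 1869, control library 3 gave 1360, BRD8 library 2 gave 1569 and BRD8 library 3 gave 1566. Genes higher numbered 2445 without control library 2, 832 without control library 3, 894 without BRD8 library 2 and 871 without BRD8 library 3. Genes lower numbered 804, 2784 and 528 without control libraries 1, 2 and 3, and 838, 675 and 695 without BRD8 libraries 1, 2 and 3. With a trend with transcript length and GC content taken out of each library, 5265 genes changed, 2394 higher and 2871 lower. Across genes, which are not independent replicates, the log2 fold change followed transcript length at a Spearman rho of -0.161, and -0.299 without control library 2. The median length was 2990 bases for genes higher and 4030 for genes lower.

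Mitotic genes fell nearly as a whole, and many replication genes fell. Of 55 measured genes of mitosis and G2/M, 53 fell and none rose, with a median log2 fold change of -0.71, and 53 fell when adjusted over the list alone. Cyclin B2 (CCNB2) fell from 2873 ± 203 to 1545 ± 70.7 normalized counts (log2 fold change -0.89, SE 0.0806). The chromosomal passenger subunit CDCA8 fell from 1595 ± 163 to 835 ± 17.8, the phosphatase CDC25C from 794 ± 63.5 to 424 ± 11.4 and the condensin subunit NCAPG from 1557 ± 135 to 877 ± 33.5. Genes of DNA replication and the G1/S transition went the same way at a smaller size, with 26 of 50 lower and none higher, 33 lower when adjusted over the list alone, and a median of -0.31. Among them the clamp loader subunit RFC3 fell by 0.74, the primase subunit PRIM1 by 0.60, the repressor E2F8 by 0.54 and the helicase subunit MCM6 by 0.39 on the log2 scale. Both lists passed the list test (camera, adjusted p = 2.86e-30 for mitosis and 5.68e-11 for replication). For each of them adjusted p = 0.107 with an estimated correlation. Replication genes lower numbered 16 and 8 without control libraries 1 and 3, 12 and 9 without BRD8 libraries 2 and 3, and 40 with the length and GC trend taken out. Without control library 2, 1 mitosis gene rose.

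p53 target genes did not move together. Of 28 measured, 3 rose and 5 fell (3 and 6 when adjusted over the list alone), with a camera adjusted p of 0.462. TP53INP1 rose by 0.71 and the antiproliferative gene BTG2 by 0.61 on the log2 scale, while the kinase PLK2 fell by 0.60 and the cyclin CCNG1 by 0.37. The p53 targets lower numbered 3 without BRD8 library 2 and 2 without each other library except control library 2. Of 28 apoptosis regulators, 4 rose and none fell, with the same counts when adjusted over the list alone and a median of 0.11 (camera adjusted p = 0.00367, adjusted p = 0.107 with an estimated correlation). Among those that rose were the BH3-only gene BIK, by 0.77, and the death ligand gene TNFSF10, by 0.32 on the log2 scale. The call for BIK ended without control library 3 (adjusted p = 0.0544) and BRD8 library 3 (0.0504). TNFSF10 lost its call without control library 1 (adjusted p = 0.0752), control library 3 (0.0950), BRD8 library 2 (0.0920) and BRD8 library 3 (0.0992). Apoptosis regulators higher numbered 2, 8 and 1 without control libraries 1, 2 and 3, 2 and 1 without BRD8 libraries 2 and 3, and 9 with the length and GC trend taken out.

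Many interferon-stimulated and inflammatory genes rose. Of 46 interferon-stimulated genes, 27 rose and none fell, with 34 rising when adjusted over the list alone and a median log2 fold change of 0.42. OAS1, a sensor of double-stranded RNA, went from 1717 ± 140 to 3333 ± 29.8 normalized counts, IFIT2 from 4083 ± 126 to 7083 ± 132, the GTPase gene GBP1 from 626 ± 47.4 to 1126 ± 53.5 and IFIT1 from 3107 ± 222 to 4818 ± 56.3. Among 27 chemokine and cytokine genes 15 rose and none fell, 17 rose and 1 fell when adjusted over the list alone, and the median was 0.38. The neutrophil chemokine CXCL6 rose from 2564 ± 30.0 to 7946 ± 491 normalized counts (log2 fold change 1.63, SE 0.0716, adjusted p = 1.25e-05), CXCL8 from 5194 ± 107 to 9457 ± 150 and the mucosal chemokine CCL28 from 687 ± 64.9 to 1578 ± 95.5. Camera gave adjusted p = 2.06e-13 for the interferon list and 6.24e-09 for the chemokine list. With an estimated correlation these were adjusted p = 0.107 and adjusted p = 0.108. The interferon-stimulated genes higher numbered 13 without control library 3, 15 without BRD8 library 2 and 13 without BRD8 library 3. With the length and GC trend taken out 1 gene of each list fell.

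In the NF-kB pathway, 8 of 30 genes rose and none fell, against 10 higher and 2 lower when adjusted over the list alone, with a median of 0.11. TNFAIP2 rose by 0.78, the adaptor MYD88 by 0.54, NFKBIZ by 0.57 and the inhibitor NFKBIA by 0.50 on the log2 scale. Camera gave adjusted p = 0.0316 (adjusted p = 0.194 with an estimated correlation), and 0.0565 without control library 3. With the length and GC trend taken out it gave 0.0822, at a median of 0.01. The median was 0.07 without control library 1 and 0.18 without control library 2. Without control library 3 or BRD8 library 3, 5 of these genes rose, while 2 fell without control library 2, 1 in DESeq2 and in the authors' deposited table, and 5 with the trend taken out. Antigen presentation genes did not move together. Of 23 measured, 3 rose and 3 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.654). The log2 fold changes of ERAP1, a peptide-trimming enzyme, and HLA-DRA were 0.37 and -0.46. Neither call held without control library 3, at adjusted p = 0.0943 and 0.106, or without BRD8 library 3, at 0.0862 and 0.0955. ERAP1 also lost it without BRD8 library 1 (0.0653) and HLA-DRA without BRD8 library 2 (0.0698). The list's rises numbered 1, 7 and 0 without control libraries 1, 2 and 3 and 0, 1 and 0 without BRD8 libraries 1, 2 and 3. Its falls numbered 0 without control library 3, 1, 0 and 0 without BRD8 libraries 1, 2 and 3, 1 in edgeR at a mean of at least 5 CPM, and 9 with the trend taken out.

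Many genes of airway secretion and defence rose. In the mucin and secretory list, 14 of 19 genes rose and 1 fell, with 16 higher and 1 lower when adjusted over the list alone, and the median log2 fold change was 0.79. AGR2, a disulfide isomerase needed for mucin production, rose from 18744 ± 2826 to 39710 ± 1733 normalized counts, the mucin gene MUC20 from 1797 ± 176 to 4200 ± 246, the mucus protein FCGBP from 85.1 ± 15.3 to 315 ± 22.6, and the fucosyltransferase FUT2 from 683 ± 76.5 to 1178 ± 74.4. MUC20 shares exons with MUC20-OT1. In the antimicrobial and innate defence list 11 of 20 genes rose and none fell, 14 rose when adjusted over the list alone, and the median was 0.61. PIGR, the receptor that carries immunoglobulins across the epithelium, rose from 447 ± 23.5 to 1487 ± 95.5 normalized counts, the defensin DEFB1 from 777 ± 168 to 2103 ± 169, and LCN2, which binds bacterial siderophores, from 6619 ± 1509 to 17079 ± 1095. CEACAM6, an adhesion molecule with close paralogs, rose by 1.45 on the log2 scale. Camera gave adjusted p = 4.21e-09 for secretion and 6.24e-09 for defence. With an estimated correlation these were adjusted p = 0.107 and adjusted p = 0.108.

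**Figure D3:**
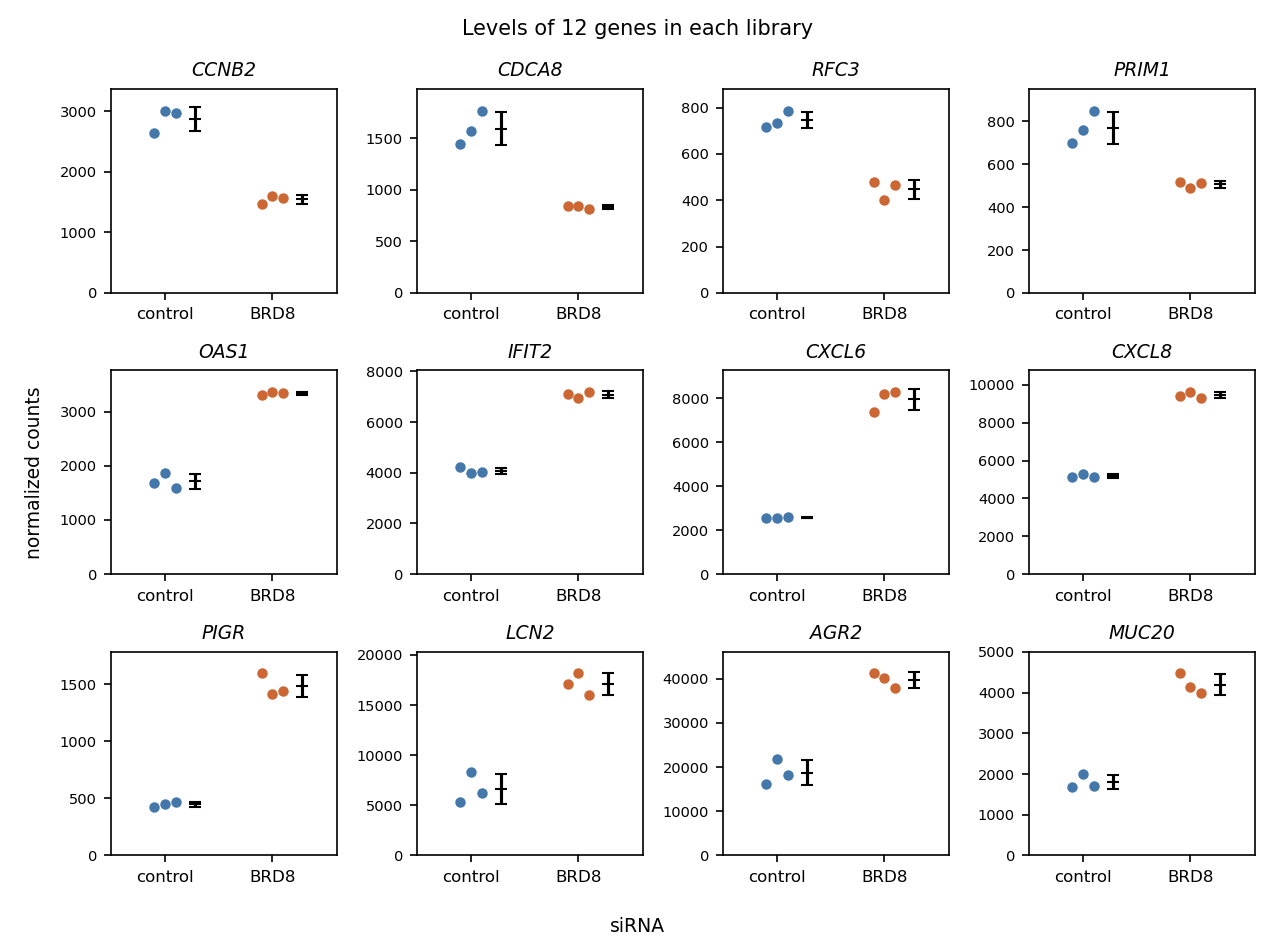
Normalized counts (vertical axes, from 0) of 12 genes in each library of the control siRNA and BRD8 siRNA groups, with the mean and SD of 3 libraries at the right of each group. The cell cycle genes in the top row fell, CCNB2 from 2873 to 1545, and the interferon, chemokine, defence and secretory genes below rose in each BRD8 siRNA library.

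Some ion transport, transcription factor and junction genes of the airway epithelium rose. Of 27 ion and fluid transport genes, 11 rose and 1 fell, with the same counts when adjusted over the list alone and a median of 0.29. The potassium channel subunit KCNE3 rose from 181 ± 3.27 to 500 ± 20.6 normalized counts, the aquaporin AQP3 by 1.24 on the log2 scale, and the carbonic anhydrases CA2 and CA12 by 0.93 and 0.49. Of 33 airway transcription factors, 12 rose and none fell, against 14 higher and 2 lower when adjusted over the list alone, with a median of 0.23. CEBPA rose by 2.03 on the log2 scale to 43.8 ± 9.10 normalized counts, the pioneer factor FOXA1 by 0.64 and ID2 by 0.51. Of 43 junction and adhesion genes, 13 rose and 2 fell (15 and 2 when adjusted over the list alone; median 0.18). E-cadherin (CDH1) rose from 15769 ± 1135 to 22051 ± 906 normalized counts, beta-catenin (CTNNB1) by 0.45 and CLDN23 by 0.93 on the log2 scale, and the desmosomal cadherin DSC2 fell by 1.04. Camera gave adjusted p = 0.00113 for transport, 3.91e-04 for transcription factors and 6.63e-04 for junctions. In the same order, adjusted p = 0.107, adjusted p = 0.158 and adjusted p = 0.173 with an estimated correlation. The median of the transcription factors was 0.13 with the length and GC trend taken out. Of the transcription factors 5 rose without control library 3 and 6 without BRD8 library 2 or 3, and 5 fell without control library 2, 1 without BRD8 library 1, 1 at a mean of at least 50, 1 with quantile normalization, 2 in DESeq2 and in the authors' deposited table, and 3 with the trend taken out. Of the junction genes 8 rose without control library 1, 6 without control library 3, BRD8 library 2 or BRD8 library 3 and 20 with the trend taken out, and 7 fell without control library 2, 1 without control library 3 or BRD8 library 2 and 4 with the trend taken out. Transport genes lower numbered 2 without control library 2 and with the trend taken out.

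The mesenchymal list showed no common direction, with 4 of 25 genes higher and 3 lower (4 and 3 when adjusted over the list alone). The matrix protein TGFBI fell from 13572 ± 1652 to 7692 ± 237 normalized counts and the receptor TGFBR1 by 0.77 on the log2 scale, while ANKRD1 rose by 0.83 and CYR61 by 0.52. The list's median was -0.01, its mean 0.03 and its camera direction upward, at adjusted p = 0.878. With the length and GC trend taken out 6 of its genes fell.

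Some genes of the secretory pathway's folding machinery also rose. In the unfolded protein response and chaperone list, 10 of 29 genes rose and none fell, 15 rose when adjusted over the list alone, and the median was 0.25 (camera adjusted p = 2.66e-05, adjusted p = 0.107 with an estimated correlation). The chaperone HSPA5 rose from 24579 ± 2116 to 35013 ± 987 normalized counts, HERPUD1 by 0.46 and calnexin (CANX) by 0.50 on the log2 scale. The rises in this list numbered 5, 18 and 3 without control libraries 1, 2 and 3, 6, 3 and 4 without BRD8 libraries 1, 2 and 3, and 20 with the length and GC trend taken out, while 2 fell without control library 2 and 1 with the trend taken out. The integrated stress response list did not pass, at camera adjusted p = 0.194, with 3 of 34 genes higher and 5 lower (3 and 6 when adjusted over the list alone). The cystine transporter SLC7A11 fell by 0.93, the serine synthesis enzyme PHGDH by 0.78, cystathionine beta-synthase (CBS) by 0.73 and the secreted glycoprotein STC2 by 0.46 on the log2 scale. The 3 rises numbered 6 without control library 2, 1 with no filter on low values and 0 without any 1 of the other 5 libraries, and the falls 8 without control library 2 and 14 with the length and GC trend taken out. This list passed downward without BRD8 library 1, at adjusted p = 0.0303, and with the length and GC trend taken out, at 0.0292 and a median of -0.15 against -0.08.

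Of 32 NRF2 and xenobiotic genes, 11 rose and 3 fell (13 and 3 when adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.00833, adjusted p = 0.359 with an estimated correlation) and of 0.10 without control library 1. The retinal dehydrogenase ALDH1A1 rose from 619 ± 33.2 to 1703 ± 191 normalized counts, AKR1B10 by 1.04 and CYP1B1 by 0.91 on the log2 scale, and ME1 fell by 0.67. In the thyroid and retinoid receptor list, 7 of 21 genes rose and none fell, against 8 higher and 1 lower when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.00486, adjusted p = 0.107 with an estimated correlation) and of 0.20 without BRD8 library 2. Those with the smallest p were RARRES2, TGM2, RARRES1 and RARRES3, named for their induction by retinoids or their transglutaminase activity, and TGM2 rose from 11126 ± 257 to 16683 ± 292. NRF2 and xenobiotic genes higher numbered 6 without control library 1 or 3 and 7 without BRD8 library 1 or 2, and 5 were lower with the length and GC trend taken out. In the receptor list 3 fell without control library 2 and 2 with the trend taken out.

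Lipid, sugar and respiratory genes did not pass the list test. For cholesterol synthesis and SREBP targets, 1 of 33 genes rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.0921). Downward, this list passed without control library 1 (0.0198), with the length and GC trend taken out (0.0292) and in fry (0.0364). The falls numbered 1 without control library 3, 2, 1 and 1 without BRD8 libraries 1, 2 and 3, 3 with no filter on low values, 2 in edgeR with upper-quartile factors and 14 with the trend taken out, where 3 rose. No member rose without control library 1 or 3 or any 1 of the BRD8 libraries. SREBF2, the main activator of that pathway, fell from 12614 ± 82.9 to 8882 ± 197 normalized counts. For hypoxia and glycolysis, 4 of 32 rose and 3 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.634), with NDRG1 higher by 0.54 and HK1 lower by 0.37 in log2 terms. The hypoxia rises numbered 2 without control library 1 or any 1 of the BRD8 libraries, 1 without control library 3 and 2 in edgeR with no filter, and the falls 5 without control library 2, 1 without control library 3, BRD8 library 1 or BRD8 library 2, and 5 with the trend taken out. For oxidative phosphorylation, none of 56 rose and 2 fell (none when adjusted over the list alone; camera adjusted p = 0.340, and 0.00328 without control library 1). The log2 fold change of COX8A was -0.45 and of NDUFS1 -0.33. Without control library 3 their adjusted p was 0.0698 and 0.119, and without BRD8 library 3 it was 0.0896 and 0.0621. It was 0.0905 and 0.0620 without BRD8 library 1, and NDUFS1 also missed without control library 1 (0.0673) and BRD8 library 2 (0.0989), and with the length and GC trend taken out (0.0676). In that list 4 fell without control library 1, 1 without BRD8 library 2, 4 with quantile normalization, 5 in DESeq2 and in the authors' deposited table and 14 with the trend taken out, and 7 rose without control library 2 and 1 with the trend taken out.

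As lists, the partners of BRD8 and the other bromodomain genes did not pass camera with all libraries and the treatment alone in the design. Over all 15354 genes tested, 1549 rose and 1371 fell. Among 17 TIP60/NuA4 partners 1 rose and 3 fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.278). Fry, which asks only whether members move on balance, gave 0.00135, downward. MEAF6 fell from 2217 ± 39.8 to 1570 ± 42.1 normalized counts (adjusted p = 0.00186), and MBTD1 had a log2 fold change of -0.52 (adjusted p = 0.0117, and 0.0599 without control library 3). The rise of 1 partner missed without each library other than control library 2, without which 3 rose and 6 fell. Partners lower numbered 1 without control library 3 and 7 with the length and GC trend taken out, and those higher 0 in edgeR with no filter, 2 at a mean of at least 5 CPM and 2 with the trend taken out. Of 37 other bromodomain genes 1 rose and 1 fell, also when adjusted over the list alone, with SP140L higher by 0.41 and ATAD2 lower by 0.66 in log2 terms. Camera gave adjusted p = 0.0785 for this list, 5.28e-04 without control library 2 and 0.0445 without BRD8 library 3, downward in each case. In it 2 rose and 17 fell without control library 2, 2 rose and 7 fell with the trend taken out, and 6 fell in DESeq2 and in the authors' deposited table, 5 in DESeq2 with no independent filtering and 3 in edgeR with no filter.

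In the CTCF and cohesin list, 4 of 13 genes fell and none rose, also when adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.00411, adjusted p = 0.503 with an estimated correlation). Fry gave 0.118, and the median was -0.15 with the length and GC trend taken out. Of the 4 falls 2 passed without each library other than control library 2, and without that library 8 genes fell. The acetyltransferase ESCO2 fell by 0.67 and the cohesin subunit RAD21 from 7257 ± 568 to 5412 ± 188 normalized counts. In the list of chromatin variants and SWR1-type remodelling, 7 of 30 fell and none rose, also when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.00365, adjusted p = 0.143 with an estimated correlation). The Polycomb subunit SUZ12 fell by 0.60 on the log2 scale. ANP32E, a chaperone of histone H2A.Z, fell by 0.37, at adjusted p = 0.00983 with all libraries and 0.0617 without control library 3. The falls in this list numbered 3, 12 and 1 without control libraries 1, 2 and 3, 4, 2 and 2 without BRD8 libraries 1, 2 and 3, 4 in edgeR with upper-quartile factors and 11 with the trend taken out, and 1 gene rose without control library 2. Of 74 cytosolic ribosomal protein genes, none passed the limma test over all genes or when adjusted over the list alone, 5 had an unadjusted p under 0.05, and edgeR called 0. Their median was -0.12 with all libraries (camera adjusted p = 0.00365, adjusted p = 0.726 with an estimated correlation) and 0.02 without control library 2, where camera gave 0.587, and fry gave 0.507 with all libraries. It was -0.21 without control library 1. Without control library 2, 1 of these genes rose, while 3 fell with quantile normalization, 1 in DESeq2 and in the authors' deposited table and 28 with the trend taken out. RPS2 had 61645 ± 7169 and 49392 ± 5200 normalized counts in control and BRD8 siRNA libraries. RPS2 passed under some other settings, among them quantile normalization (adjusted p = 0.0195), DESeq2 (0.0343) and the length and GC trend taken out (1.50e-04). Without BRD8 library 3 the list's adjusted p was 0.104, at a median of -0.07.

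Markers of other cell types were measured as a check of identity. A mean of at least 10 over both groups was reached by 10 of 11 basal, 12 of 21 ciliated and 8 of 13 alveolar markers. It was reached by 5 of 16 leukocyte, 3 of 14 fibroblast and endothelial and 9 of 16 liver and intestinal markers. The counts below cover these genes only. Of 10 basal airway markers, 6 rose and none fell, also when adjusted over the list alone, with a median of 0.71 (camera adjusted p = 0.00273, adjusted p = 0.246 with an estimated correlation). The keratin KRT17 rose from 25434 ± 3866 to 62049 ± 4790 normalized counts, KRT14 from 303 ± 63.5 to 756 ± 66.9 and S100A2 from 5251 ± 1362 to 10499 ± 1025. Of 9 liver and intestinal markers, 5 rose and none fell, 7 rose when adjusted over the list alone, and the median was 0.64 (camera adjusted p = 3.91e-04, adjusted p = 0.107 with an estimated correlation). Albumin (ALB) rose from 6.49 ± 2.91 to 67.6 ± 12.6 normalized counts, villin (VIL1) by 0.71 and SERPINA1 by 0.64 on the log2 scale. With a control mean below 10, ALB passed the filter on the mean of both groups only through its level in the BRD8 siRNA libraries. Such genes can enter a list by rising, which favours rises in the counts. The liver and intestinal rises numbered 3 without control library 3, BRD8 library 1 or BRD8 library 2, and 2 at a mean of at least 50 normalized counts and in edgeR at a mean of at least 5 CPM.

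The remaining marker lists did not pass the list test. Of 12 ciliated cell genes 1 rose and 3 fell, of 8 alveolar genes 1 rose and 1 fell, and of 5 leukocyte and 3 fibroblast and endothelial genes 1 rose in each, with the same counts when adjusted over each list alone. Camera gave adjusted p = 0.278, 0.532, 0.278 and 0.532 in that order. RSPH1, a ciliary gene, rose by 0.66 and RTKN2, an alveolar marker, fell by 0.72 on the log2 scale. No ciliated cell gene fell without control library 1 or 3, 1 fell without BRD8 library 1 or 2, and 2 rose without control library 2. The alveolar gene that rose missed without control library 3 or any 1 of the BRD8 libraries, and 2 rose without control library 2. In edgeR at a mean of at least 5 CPM 1 ciliated gene fell, and no gene of the ciliated, alveolar or fibroblast and endothelial lists rose. In the last of these lists no gene rose at a mean of at least 50 and 2 rose with no filter, where 1 leukocyte gene fell. CD68 was at 1486 ± 189 normalized counts in control and 1926 ± 155 in BRD8 siRNA libraries, and lysozyme (LYZ) at 17527 ± 787 and 17011 ± 271. LYZ is also a member of the airway antimicrobial and innate defence list. LUM was at 28.5 ± 4.18 and 54.7 ± 10.9. The rise of CD68 passed the test only with all libraries or without control library 2, and its adjusted p was 0.0612 to 0.138 without each of the others. That of LUM did not pass without control library 3 (adjusted p = 0.0519), BRD8 library 1 (0.0737) or BRD8 library 3 (0.0751).

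**Figure D4:**
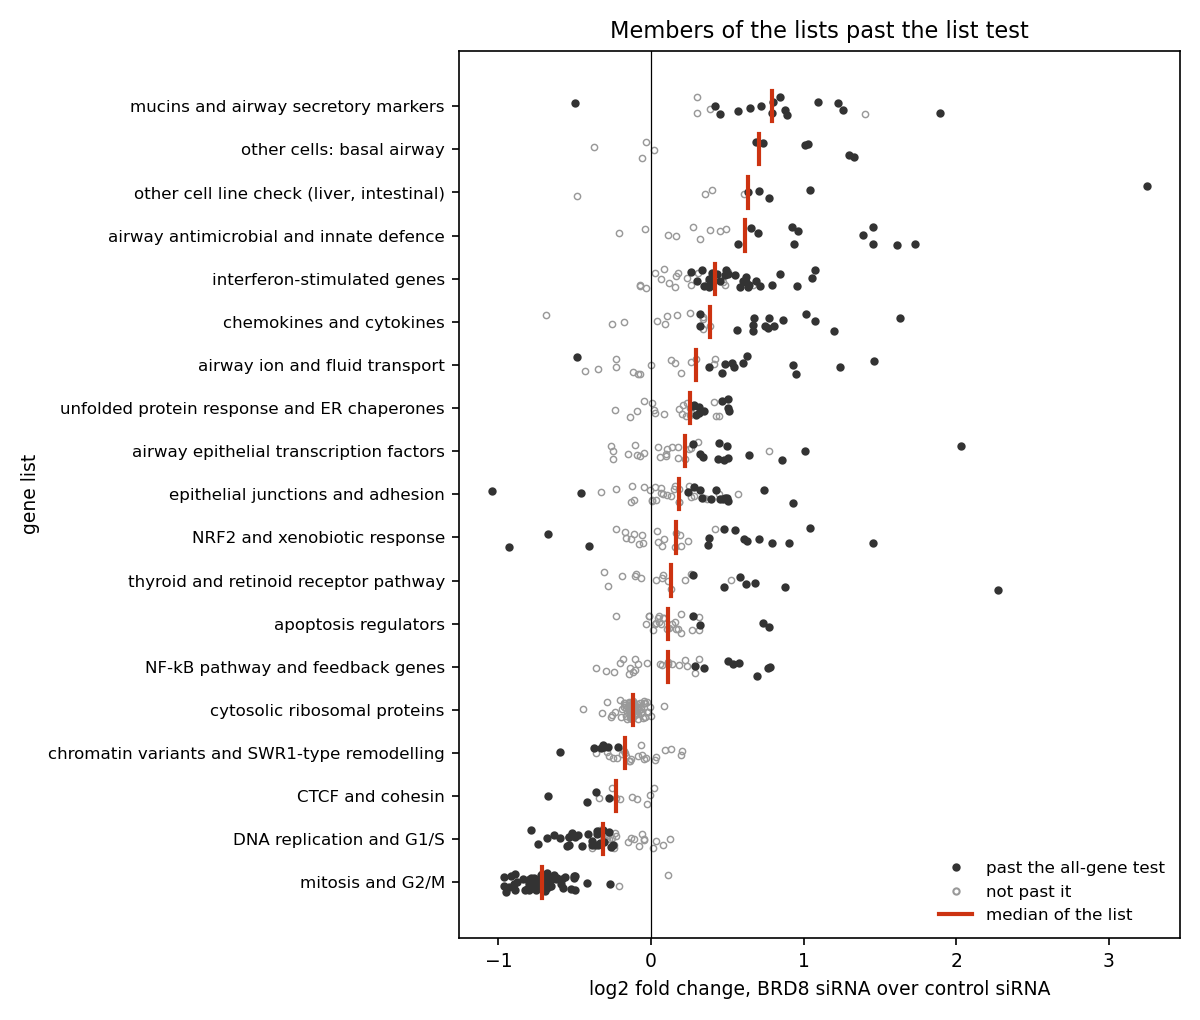
Log2 fold change of BRD8 siRNA over control siRNA (horizontal axis) for each measured member of the 19 gene lists that passed the list test (vertical axis, ordered by median). Filled points passed the test over all genes, open points did not, and red bars mark the list medians, from -0.71 for mitosis and G2/M to 0.79 for mucins and secretory markers.

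In all, 19 of the 32 lists passed camera with its preset correlation, and fry passed 19. With a correlation estimated in each list 0 of 32 passed camera, and 11 had an unadjusted p under 0.05. A larger correlation within lists does not account for every loss. The chaperone, apoptosis and thyroid and retinoid lists had estimated correlations of -0.0107, -0.0202 and -0.0311, below the preset 0.01, and missed as well. For a simulated list of 50 genes moved by 0.4, camera gave p = 2.49e-49 with the preset and 7.96e-05 with the estimated correlation. The estimated form was the weaker test there too. Other divisions of the 6 libraries into 3 and 3 put up to 16 lists past the preset test. Each of them holds both treatments in both groups, so this is not the count without a treatment difference.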

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

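The minimum folds, the filters, the other count models, the scalings, the left-out libraries, fry and the estimated correlation were planned; edgeR with TMM, the authors' deposited comparison, quantile normalization for the lists and the trend with length and GC were chosen after the data were seen. Across left-out libraries the changed genes ranged from 1360 without control library 3 to 5229 without control library 2, those higher from 832 to 2445 and those lower from 528 to 2784; each such fit has fewer samples. A minimum log2 fold change of 1 left 329 genes, and an edgeR test against 0.58 left 197. With the length and GC trend taken out, 5265 changed, 2394 higher and 2871 lower. At a mean of at least 5 CPM, 10 of the 24 named largest changes stayed, since fewer genes were tested (11209). With an estimated correlation 0 lists passed. With the replicate block 3901 genes and 20 lists passed, other bromodomain genes at adjusted p = 0.0206 and RPS2 at 0.0112; 8 other bromodomain, 7 CTCF and cohesin, 8 integrated stress response, 5 oxidative phosphorylation and 2 ribosomal protein genes were lower with it, as were 2 airway transcription factors and 1 gene each of the NF-kB, chaperone and receptor lists, and 7 apoptosis, 16 chaperone and 1 oxidative phosphorylation genes higher; same-numbered libraries correlated at -0.08, 0.34 and 0.15, and not every library correlated best with its own number. The direction of the list test turned for mesenchymal genes (median -0.0243 at 5 CPM and -0.00461 with quantile normalization), alveolar markers (0.0247 at 5 CPM), antigen presentation (0.0139) and hypoxia (-0.0302) with the trend taken out; of these medians only that of hypoxia changed sign. Over left-out libraries antigen presentation ranged from -0.00689 without BRD8 library 2 to 0.131 without control library 2, hypoxia from -0.0191 without control library 1 to 0.123 without control library 2, ribosomal proteins from -0.211 without control library 1 to 0.0184 without control library 2 and oxidative phosphorylation from -0.101 without control library 1 to 0.0374 without control library 2. The cause of these turns was not tested. The fibroblast and endothelial list gave no value at 5 CPM. BRD8 fell in every fit run. Of the named genes' results, 768 with a library left out and 2420 under other settings kept direction and side of the threshold, while 110 and 18 lost the call and 4 and 27 gained it; none turned. The floor of 3 reads lies at 2.84 to 3.24 normalized counts, and how depth limits genes above it was not tested by level.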

Other observations

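The gene families, the genes named in this part, the words of 7 bases, the base composition tests and the counts of splits were chosen after the results were seen, as was the fit with the length and GC trend taken out, while what the tests of that trend, of depth, of the siRNA seed and of the mitotic genes would show was written before their results.

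Genes outside the naming rule, chosen after their values were seen, moved too. CFTR, the chloride channel of the airway surface, rose from 26669 ± 3406 to 40351 ± 3166 normalized counts (log2 fold change 0.60, adjusted p = 0.00583). HPGD, which inactivates prostaglandins, rose from 354 ± 22.5 to 1350 ± 27.2 normalized counts, the estrogen sulfotransferase gene SULT1E1 from 251 ± 3.53 to 910 ± 30.9 and SPTSSB, a subunit of serine palmitoyltransferase, from 3912 ± 65.6 to 12288 ± 323. These rises passed the test with each library left out in turn, with adjusted p up to 0.0325 for CFTR.

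In several families of genes with a shared symbol stem, the members that passed the test went mostly 1 way. Of 260 families tested, kallikreins rose in 6 of 8 members with a median log2 fold change of 1.08 to 1.27 over the scalings, KLK7 by 1.92 and KLK11 by 1.29 on the log2 scale. Keratins rose in 13 of 29 (median 0.38), aldo-keto reductases in 8 of 12 (0.58) and cytochromes P450 in 13 of 33, with 1 lower (0.33). Kinesins fell in 16 of 33 (median -0.35), KIF15 by 0.89 and KIF23 by 0.73. Each median kept its sign in 5 of 5 other scalings, and camera gave adjusted p between 1.56e-06 for kinesins and 0.00220 for cytochromes. With an estimated correlation adjusted p = 0.922 for each, and reads shared among paralogs leave single members uncertain.

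Control library 2 stood apart from the other control libraries, and its deviation from their mean correlated with transcript length at a Spearman rho of -0.556. With GC content it correlated at 0.476, across genes, which are not independent replicates. The trend was not that of 1 library. Against the mean of all libraries, control library 2 deviated with length at -0.384 and BRD8 library 2 at -0.340, and with GC at 0.295 and 0.364. Control libraries 1 and 3 deviated with length the other way, at 0.401 and 0.312. BRD8 libraries 1 and 3 gave -0.0704 and 0.0586. With group means taken out, control library 2 and BRD8 library 2 correlated at 0.335, each the best match of the other across groups. The labels state no batch, and whether these libraries shared one was not tested. The log2 fold change itself followed length (-0.161, and -0.299 without control library 2). With libraries thinned to one total, control library 2 against the other control libraries again gave -0.556 with length, which argues against lower depth. Without this library the changed genes rose from 2874 to 5140, a ratio of 1.79, among genes with a length and GC; with the trend taken out of each library they went from 5265 to 5769, a ratio of 1.10. A trend with length and GC may therefore account for how this library moves the count; its origin, in RNA quality or library preparation, was not tested.

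Genes with either of a pair of words in the 3' untranslated region were lower after BRD8 siRNA. Log2 fold changes were first limited to 1.5 either way. They were then adjusted by regression for mean level and for the length and GC content of transcript and 3' untranslated region. In these adjusted values GACTATT had the lowest z of 16239 words, -6.11, over 1133 genes with a mean difference of -0.07. TGTCATT had -5.98 over 2717 genes. Unadjusted, the median log2 fold change was -0.110 with GACTATT and -0.00844 without it, and -0.0972 and 0.00314 for TGTCATT. For base composition of the 3' UTR, 0 other words made of the bases of GACTATT and 0 of those of TGTCATT had a z as low; the words were picked for the lowest z, so that count decides nothing and composition stays open. A candidate explanation is a seed match of a BRD8 siRNA, GACTATT occurring in 8 of 11 protein coding BRD8 transcripts, and likewise a seed match of a BRD8 siRNA, TGTCATT occurring in 7, though 31.8% of all words occur in at least 1 BRD8 transcript. The match stays open, since 1 of 100 shuffles had a word as low as each (lowest z -6.12) and the siRNA sequences are not given in the sources used here. The median over the shuffles of the lowest z was -3.86.

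The fall of mitotic and replication genes remained with the length and GC trend taken out, at a median log2 fold change of -0.73 for mitosis, which argues against that trend as its whole cause. The 42 of 55 mitosis genes with neither word had a median of -0.71 (quartiles -0.80 and -0.65), and 43 replication genes with neither word a median of -0.31. These medians argue against matches to these words in the genes themselves as the whole cause of the fall. Seed matches to other words stay open, since the siRNA sequences are not given in the sources used here. An effect of this siRNA reagent other than BRD8 loss cannot be told apart from BRD8 loss, since the design holds 1 reagent against BRD8. Loss of BRD8 may lower these genes, directly or through slower division, and neither was tested.

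The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2920 changed genes, 1549 higher and 1371 lower, and 19 lists, and was the 1 split with results as large for each of these; the highest among other splits was 0 genes, 0 higher, 0 lower and 16 lists. The 0 is the count by limma and also by edgeR. At an unadjusted p under 0.05 limma gave 35 to 2323 genes in the other splits, against 5084 in the real one. Each other split holds both treatments in both groups. That leaves part of the treatment difference between its groups and widens the spread within them. Its counts of genes and lists are therefore not those expected without a treatment difference.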
